A study of Mus musculus with 18 samples.

How the data were processed

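Expression was measured with 1-colour arrays of the type Affymetrix Mouse Gene 1.0 ST, whose probe sets cover whole transcripts. Per the labels' protocols, spleen or peritoneal lavage cells of male C57BL/6 mice aged 6 weeks were stained with antibodies and sorted by FACS directly into TriZol, a reagent for RNA extraction. All 18 arrays carried the label of 2 h after 10000 U of IFNg, and they fell into 9 populations of 2 arrays each, grouped by title. Labels give the gates as CD11c+ MHC class II+ Flt3+ for DC, Ly6G+ for GN, F4/80+ ICAM2+ for MF, NK1.1+ TCRB- for NK, NK1.1+ TCRB+ for NKT, CD4+ TCRB+ for T4, CD8+ TCRB+ for T8, TCRgd+ TCRB- for Tgd and CD4+ TCRB+ CD25+ for Treg. The series text speaks of a time course and of 11 populations. Other times, 2 of those populations and untreated animals were not analysed here.

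The deposited values were intensity values on a linear scale, 1 per probe set and array, made with Affymetrix Power Tools and RMA (background correction, normalization and summary of the probes of a set) per the submitters' processing notes. Versions were not given in the sources used here, nor whether all 18 arrays were normalized together. The table held 24922 probe sets, with no missing value and none at or below 0. Intensities reached between 14319 and 18280 at the maximum of each array, and log2 was taken before every test. These values settled the scale. RMA compresses differences of dim genes, so that folds near the background understate the change.

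Probe sets were named through GEO's platform annotation, with symbols updated by Entrez number against an NCBI RefSeq gene table of assembly GRCm38.p6, which was used for names and for which genes neighbour each other. Of the probe sets, 21425 had 1 gene symbol, 1399 had several and 2098 were not listed with a gene. The reference held 21347 of the single symbols by Entrez number. Genes were named and tested only from probe sets with 1 symbol. For the 921 genes with more than 1 such probe set, the one with the highest mean over all arrays was used, which left 19752 genes. Probe sets with several symbols, which include several GTPase and MHC class I genes, were not named. Of these, 695 of 1399 passed the test over the 9 populations, as did 646 of the 2098 without a listed gene. In the gene lists described below, 12 of 20 GTPases and 13 of 19 MHC class I genes were thus measured, and list counts refer to measured members. Where the probe sets of a gene named by the rule below differed in size in a contrast, the report gives the other value. Ranges of the F tests and genes given as examples were not checked in this way.

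Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on all 18 arrays with 1 mean per population and no covariate. The arrays shared 1 estimate of the spread per gene, with 9 residual and 7.69 prior degrees of freedom, because each population had only 2 arrays. Moderated F tests were run over the 9 populations and over the 6 lymphoid ones. Two-sided moderated contrasts set the 3 myeloid against the 6 lymphoid populations, each population against the mean of the other 8, and related populations against each other in 6 further contrasts. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 over all genes and at least a 2-fold difference, or a 2-fold range of population means for F tests. Every p of a gene is an adjusted p of limma and every p of a list one of its camera test, unless fry is named. Every p of a correlation, adjusted or not, is a permutation p. The one-against-8 contrasts share their arrays, so their calls were not compared with one another.

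The 27 gene lists were fixed together with the tests, thresholds and alternatives before the data were examined. Among them, 8 hold interferon genes (interferon-inducible GTPases, MHC class I presentation, MHC class II presentation, chemokines, feedback and checkpoint genes, interferon-gamma receptor and signalling, type I interferon-stimulated genes and macrophage effector genes). The other 19 are immediate early and stress genes, cell cycle genes, the sort genes, markers of each of the 9 populations, and markers of B cells, monocytes, plasmacytoid dendritic cells, eosinophils and mast cells, red blood cells and platelets, stromal and mesothelial cells, and red pulp macrophages. Lists were tested with camera at a preset inter-gene correlation of 0.01 in the myeloid contrast and the 9 one-against-8 contrasts, with adjustment over the 270 tests. Of these, 169 passed, and 27 passed with a correlation estimated for each list. Where the report counts the members of a list that passed, the count is over all genes. The count in brackets is the number that passed with p adjusted over the list alone.

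Genes were named by a fixed rule among those past the threshold, without clone, microRNA and small RNA names unless on a list. For the 2 F tests it takes the 3 members of each interferon list with the largest range of population means. For each one-against-8 contrast it takes the 3 largest positive differences and the most negative one, with the highest and lowest member of the interferon lists. For the myeloid contrast it takes 10 in each direction, and for each of the 6 further contrasts 5 in each direction, with arrays that do not overlap between the sides. The 6 further contrasts add up to 6 members of the interferon lists. The rule also names the sort genes and Ifngr1, Ifngr2, Jak1, Jak2, Irf1, Socs1 and Ifng, and a further gene that is not reported here. Other list members given as examples, and Fos, Ighm, Dusp1, Mrc1, Kit, Cma1, Mmp9, Pf4 and Nos2, were chosen after their values were seen.

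Receptor and kinase levels were correlated with the GTPase level over the 9 population means in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, by two-sided permutation of the pairings with 1e+05 resamples and adjustment over 4 relations. Alternatives for the values were a further quantile normalization, median centring, every probe set on its own, and 2 filters on dim genes, the median of all values and an intensity of 120. Alternatives for the tests were no minimum fold, eBayes without the trend or with robust variance, array weights, only the populations compared, the replicate number as a block, and each array left out in turn. Lists were also tested with fry and with an estimated correlation. The correlations were repeated with list means, over the lymphoid populations, and without the 2 farthest populations. Fits without the DC arrays or without immediate early genes, and correlations and the other lists with 1 array left out, were added after the data were seen.

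The procedure was tested on simulated data with the real genes' spreads, in which the compared populations shared 1 mean per gene except for seeded changes. Among 19752 genes 66, 67 and 67 were changed by log2 values of 1, 1.5 and 2 in size. At these sizes the share recovered was 92.4%, 98.5% and 100% for T8 against T4, 95.5%, 100% and 100% for Treg against T4, 97%, 98.5% and 100% for NK against the other 8, and 100% at each size for myeloid against lymphoid. Recovery was judged by adjusted p and sign, without the minimum fold. By adjusted p alone 13, 8, 9 and 5 unchanged genes passed in these 4 contrasts, in the same order, and by the whole threshold 2 for T8 against T4 and 0 for the other 3. For the list test, the GTPases were lowered by a log2 value of 1.5 in simulated NK arrays. That list gave a camera adjusted p of 1.12e-56, and 0 of 26 other lists passed, adjusted over the lists of that contrast alone. The simulated noise was independent between genes, so this does not test lists of correlated genes. In the real data 169 list calls fell to 27 with an estimated correlation.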

Results

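Transcript levels were measured on 18 Affymetrix Mouse Gene 1.0 ST arrays, 2 for each of 9 immune cell populations sorted from male C57BL/6 mice aged 6 weeks, 2 h after 10000 U of interferon gamma (IFNg) was given under the skin. IFNg is a cytokine of T and NK cells that signals through a receptor of the chains Ifngr1 and Ifngr2 and the kinases Jak1 and Jak2. From spleen came dendritic cells (DC), Ly6G+ granulocytes (GN), NK cells (NK), NK1.1+ T cells (NKT), CD4+ T cells (T4), CD8+ T cells (T8), gamma delta T cells (Tgd) and CD25+ CD4+ T cells (Treg). Macrophages (MF) came from the peritoneal cavity, so that tissue and cell type could not be told apart for them. Arrays of untreated mice were not analysed here, and the comparisons address how interferon-responsive and identity genes differed between populations of treated animals, not how far any gene responded to IFNg. The median probe set intensity lay between 138.5 and 151.0 on every array, and the 100 brightest probe sets held between 7.45% and 8.29% of the total signal. Pearson's r between the 2 arrays of a population lay between 0.9901 and 0.996, and between arrays of different populations it lay between 0.8264 and 0.9909. With 2 arrays per population, the number of arrays limits the precision. The labels do not say that the arrays came from separate mice, so p-values measure only the spread between these arrays, which may be technical. Levels are given as mean log2 intensity ± SD (n = 2 arrays per population), and differences as log2 differences ± SE from limma.

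Genes of the sort markers were brightest in the populations sorted on them. Flt3, a cytokine receptor of dendritic cells, stood at 11.61 ± 0.10 in DC and Klrb1c, which encodes NK1.1, at 12.57 ± 0.01 in NK and 12.11 ± 0.03 in NKT. Ly6g reached 12.89 ± 0.14 in GN, Adgre1 (F4/80) 12.76 ± 0.03 and Icam2 11.59 ± 0.03 in MF, Cd8a 12.26 ± 0.03 in T8, and Cd4 11.99 ± 0.27 in T4 and 11.71 ± 0.03 in Treg. Il2ra, the CD25 chain, stood at 12.66 ± 0.18 in Treg. Some were bright elsewhere too. Itgax (CD11c) reached 12.27 ± 0.12 in DC and 11.87 ± 0.18 in NK, Il2ra stood at 11.00 ± 0.01 in T4, and Ly6g had a mean of 8.94 ± 1.86 in DC, where its values were 7.63 on replicate 1 and 10.26 on replicate 2. All 11 measured sort genes differed between populations (11 adjusted over the list alone), as did 12 of 12 granulocyte markers, 13 of 13 MF markers, 11 of 11 DC markers, 11 of 11 NK markers, 8 of 8 markers each of NKT, T4 and T8, 12 of 12 Treg markers and 5 of 6 Tgd markers, with the same numbers adjusted over the list alone.

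**Figure D1:**
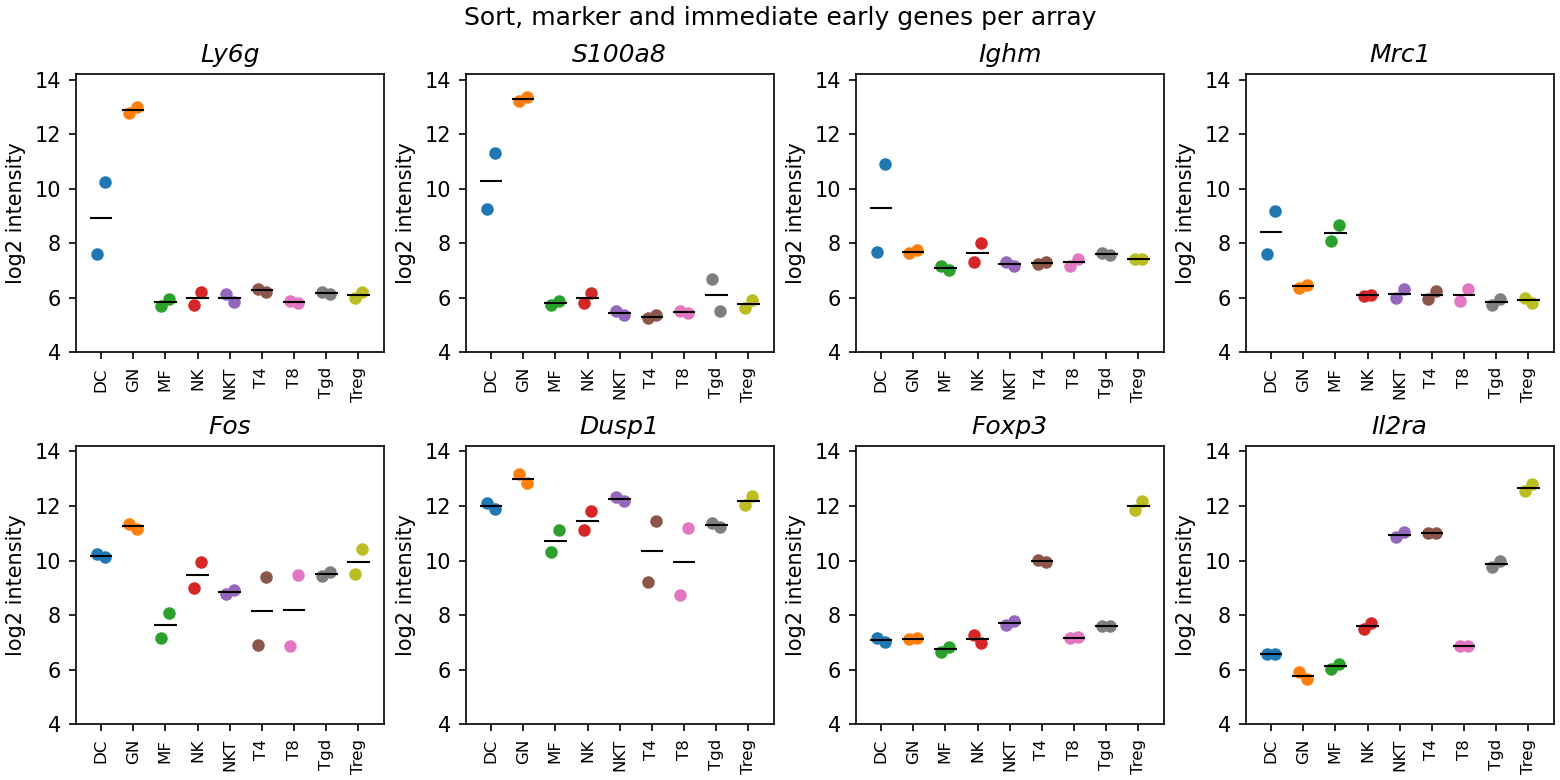
Log2 intensity (y axis) of Ly6g, S100a8, Ighm, Mrc1, Fos, Dusp1, Foxp3 and Il2ra in the 9 sorted populations (x axis), with each point 1 array and each line the mean of 2 arrays. The DC arrays lie apart for Ly6g (7.63 and 10.26), and the T4 arrays for Fos (6.91 and 9.40).

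The receptor chains of IFNg and its first signalling genes differed between populations. Ifngr2 ranged from 7.16 ± 0.25 in NK and 7.30 ± 0.09 in NKT to 11.45 ± 0.06 in GN, a range of 4.29 (adjusted p = 3.81e-15), while Ifngr1 ranged over 1.60, from 10.56 ± 0.26 in MF to 12.15 ± 0.08 in NK (adjusted p = 1.59e-09). Jak2 was highest in DC at 11.85 ± 0.11 and lowest in MF at 9.56 ± 0.05 (adjusted p = 1.05e-10). Jak1 ranged over 1.59 (adjusted p = 5.85e-11). Irf1, a transcription factor induced by interferons, was lowest in NK at 11.03 ± 0.18 and highest in GN at 12.91 ± 0.07, and Socs1, an inhibitor of this pathway, was lowest in NKT at 8.96 ± 0.12 and NK at 8.97 ± 0.14 and highest in GN at 11.71 ± 0.18 (adjusted p = 1.85e-10 and 1.06e-09). Ifng itself stood at 12.14 ± 0.28 in NK, 11.57 ± 0.79 in NKT and 9.99 ± 0.08 in Tgd. In T8 its mean was 8.30 ± 1.60, and the other populations lay between 6.31 and 7.89. Of the 15 measured receptor and signalling genes 12 passed in the test over all 9 populations (12 adjusted over the list alone). The moderated F test of limma was used, and a gene passed with an adjusted p under 0.05 and at least a 2-fold range of population means.

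**Figure D2:**
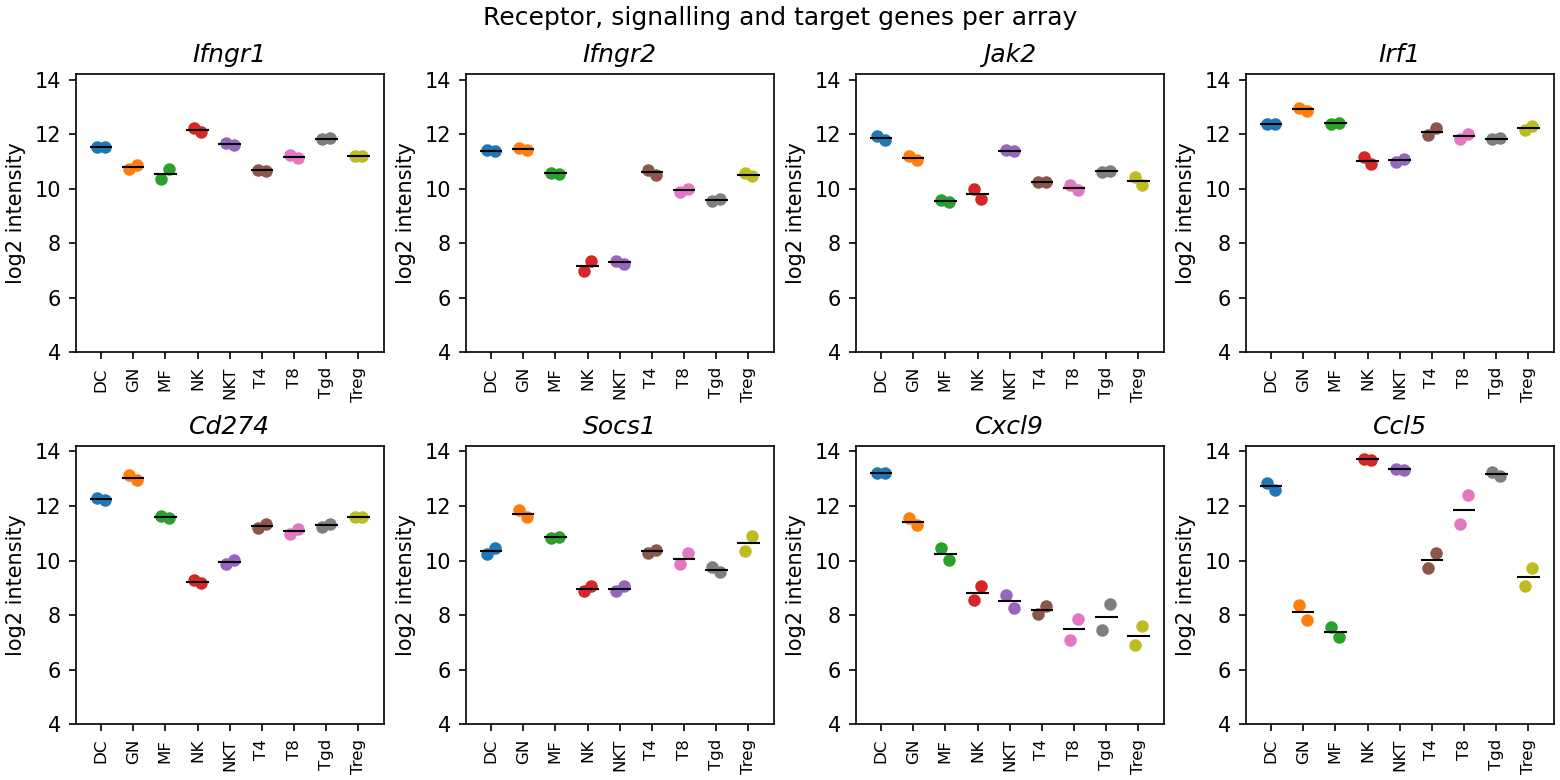
Log2 intensity (y axis) of Ifngr1, Ifngr2, Jak2, Irf1, Cd274, Socs1, Cxcl9 and Ccl5 in the 9 sorted populations (x axis), with each point 1 array and each line the mean of 2 arrays. Ifngr2 stands at 7.16 in NK and 7.30 in NKT and at 9.60 or above in every other population, while Cxcl9 is highest in DC at 13.20 and Ccl5 in NK at 13.71.

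Interferon-responsive genes differed widely over the 9 populations. Gbp2b, a guanylate-binding protein of host defence, ranged from 5.80 ± 0.05 in NK to 11.48 ± 0.13 in MF, and the immunity-related GTPase genes Iigp1 and Gm4951 ranged over 5.06 and 5.16. The MHC class II genes H2-Ab1 and H2-Aa were highest in DC at 13.48 ± 0.01 and 13.41, and Cd74, the invariant chain, ranged over 5.45. Class I presentation genes varied less: H2-Q4 ranged over 2.00, from 9.25 ± 0.02 in MF to 11.25 ± 0.05 in Treg, Psmb9 over 1.67 and the peptide transporter Tap1 over 1.59. Among the chemokines Ccl3 ranged over 7.18, Ccl5 over 6.33 and Cxcl9 over 5.95. Of the feedback and checkpoint genes, Socs2 ranged over 4.36, Cd274 (PD-L1) from 9.22 ± 0.08 in NK to 13.04 ± 0.12 in GN, and Socs3 from 8.36 ± 0.12 in NKT to 12.17 ± 0.10 in GN. The type I interferon-stimulated antiviral genes Oas2, Oasl2 and Rsad2 ranged over 5.53, 5.48 and 5.29, each with its highest mean in GN and its lowest in NK. Cybb, the catalytic chain of the phagocyte oxidase, ranged over 6.42, Il15 over 6.25 and Casp4 over 6.25. The signalling genes Irf8 and Stat2 ranged over 3.45 and 2.83. All 12 GTPases, all 9 class II genes, all 10 feedback genes, 25 of 27 type I genes, 13 of 14 macrophage effector genes, 10 of 11 chemokines and 9 of 13 class I genes passed, with the same numbers adjusted over the list alone. All 15 immediate early genes and all 13 cell cycle genes passed as well (15 and 13 adjusted over the list alone). In all, 7695 of 19752 genes passed the test over the 9 populations.

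**Figure D3:**
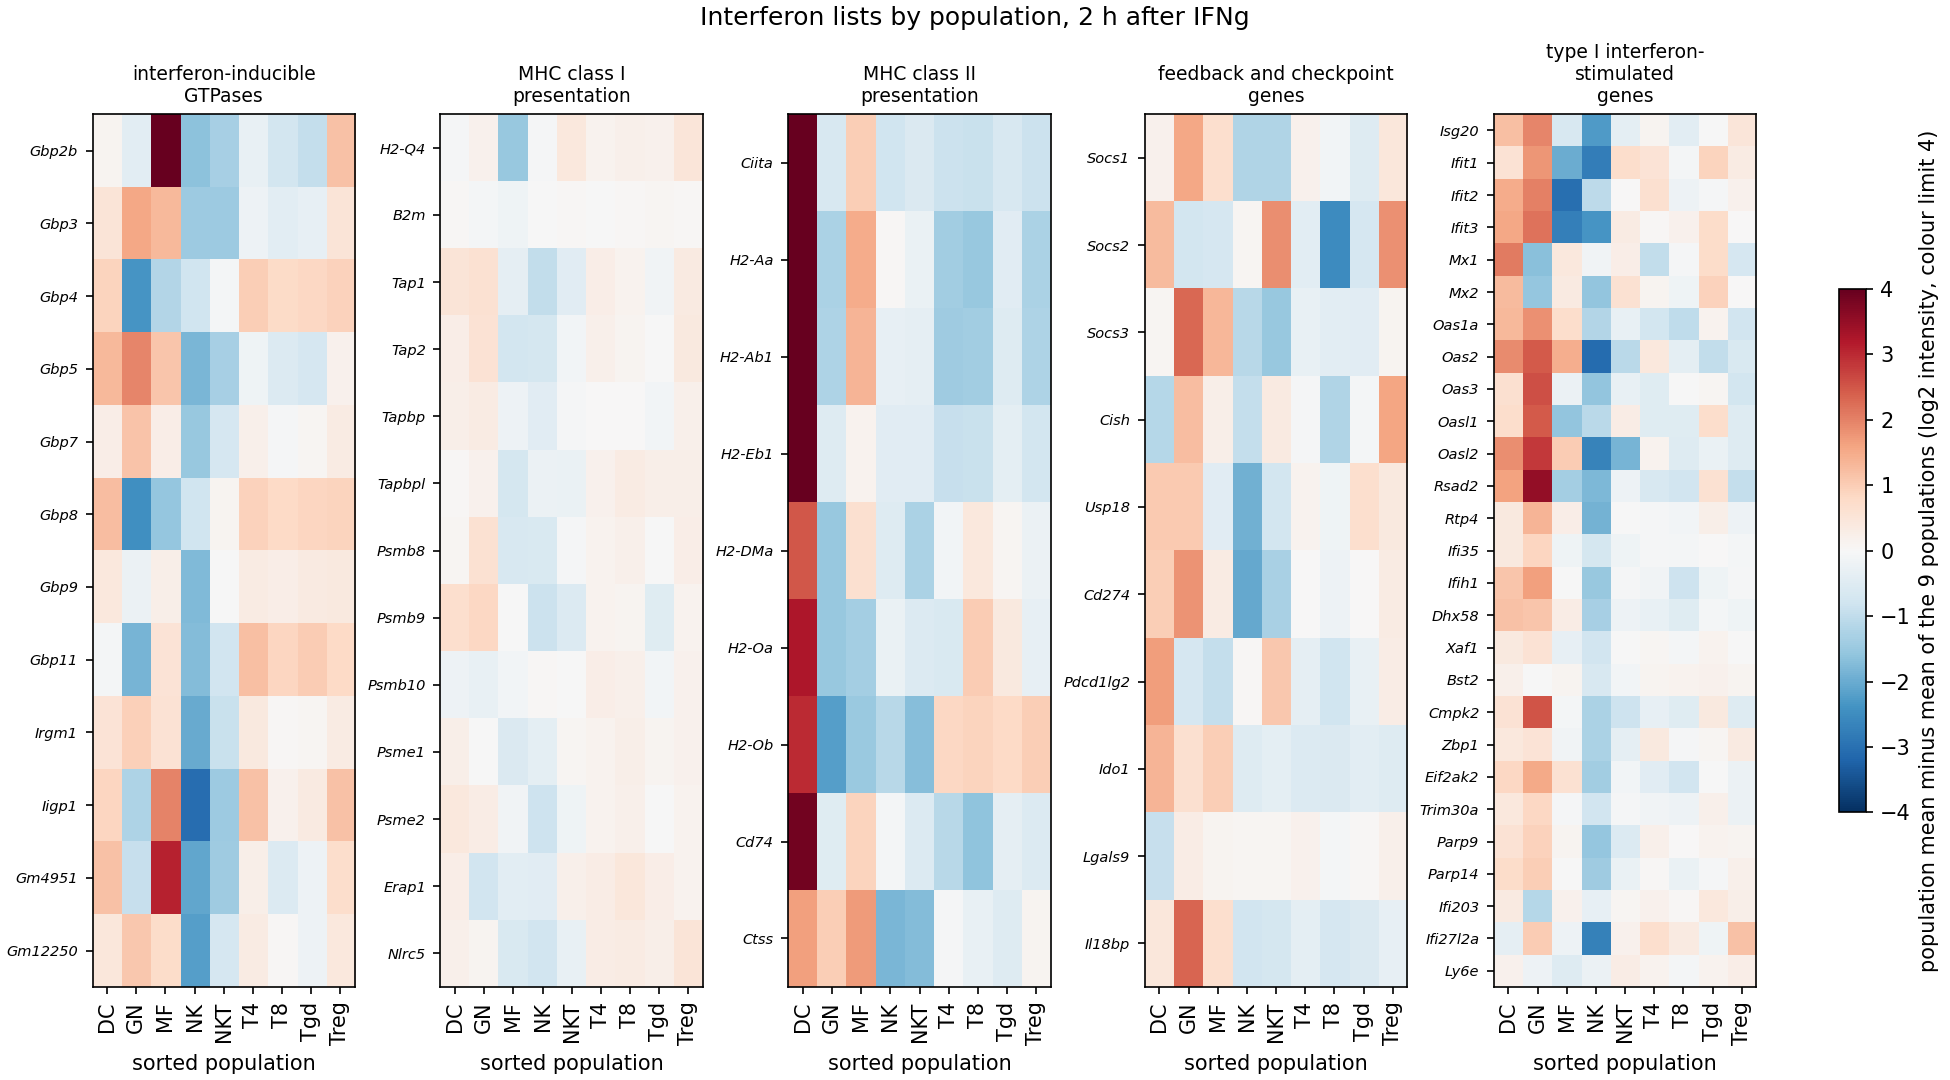
Heat map of the measured members of 5 interferon lists (y axis) in the 9 populations (x axis), as population mean minus the mean of the 9 population means in log2 units, with colours limited to values from -4 to 4. Of the class II genes 8 of 9 are highest in DC, where H2-Ab1 stands at 13.48, and of the type I genes 20 of 27 are highest in GN.

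Interferon genes differed among the 6 lymphoid populations as well. Iigp1 ranged over 4.23, from 6.76 ± 0.09 in NK to 11.00 in Treg, the pseudogene Gbp11 over 2.96 and Gbp2b over 2.80. Ifngr2 ranged over 3.44, Irf8 over 3.19 and Stat2 over 1.97. The type I genes Ifi27l2a, Ifit1 and Oas2 ranged over 3.87, 3.66 and 3.49, and the negative regulators Socs2, Cish and Usp18 over 4.36, 2.77 and 2.58. The chemokines Ccl3, Ccl4 and Ccl5 ranged over 7.18, 4.37 and 4.32. Casp1, Casp4 and Il15 ranged over 3.41, 2.78 and 2.15, the class II genes H2-Ob, Ctss and H2-DMa over 2.69, 1.93 and 1.70, and Tap1, Nlrc5 and Tap2 of class I presentation over 1.35, 1.29 and 1.10. All 12 GTPases, 21 of 27 type I genes, 7 of 10 feedback genes, 7 of 9 class II genes, 7 of 15 signalling genes, 6 of 14 macrophage effector genes, 4 of 11 chemokines and 4 of 13 class I genes passed, with the same numbers adjusted over the list alone. The B cell markers Cd79b, Ms4a1, Cd79a and Cd22 passed too, with ranges of 2.85, 2.04, 1.43 and 1.15. So did the immediate early genes Fosb, Nr4a1, Dusp1, Dusp2 and Btg2, while the other measured members of both lists did not. In total 1965 genes passed.

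DC differed from the mean of the other 8 populations most in genes of dendritic cell identity. Dnase1l3, a secreted nuclease, was higher by 6.68 ± 0.14 (adjusted p = 3.79e-16), Kmo, an enzyme of tryptophan breakdown, by 6.45 ± 0.11 and Havcr2 (TIM-3) by 6.17 ± 0.12, and the T cell receptor chain gene Cd3g was lower, at -4.84 ± 0.17. All 9 MHC class II genes were higher (9 adjusted over the list alone), among them H2-Ab1 by 5.76 ± 0.21 (adjusted p = 2.42e-13), H2-Aa by 5.22 ± 0.28 and Ciita, their transactivator, by 4.79 ± 0.09. The class II list had a median difference of 4.33 (camera adjusted p = 4.75e-15, adjusted p = 0.0356 with an estimated correlation). DC were gated on MHC class II, so the sort itself selected for this difference. Of the 11 chemokines 7 were higher (7 adjusted over the list alone), including Cxcl9 by 4.47 ± 0.23 and Cxcl16 by 3.52 ± 0.16, with a list median of 1.08 (adjusted p = 2.35e-06, and adjusted p = 0.0836 with an estimated correlation). Of the signalling genes 5 of 15 were higher (5 adjusted over the list alone), Jak2 by 1.46 ± 0.09, with a list median of 0.39 (adjusted p = 3.69e-06, and adjusted p = 0.0635 with an estimated correlation). Of the GTPases 3 of 12 (3 adjusted over the list alone) and of the type I genes 11 of 27 (11 adjusted over the list alone) were higher, with medians of 0.60 and 0.78 (adjusted p = 2.54e-06 and 5.73e-15, but adjusted p = 0.2 and 0.127 with an estimated correlation). Of the 14 macrophage effector genes 9 were higher (9 adjusted over the list alone), with a median of 1.48 (adjusted p = 2.45e-11, adjusted p = 0.0429 with an estimated correlation). Cish, a cytokine signalling inhibitor, was lower, at -1.29 ± 0.17 (adjusted p = 1.13e-05). Without DC replicate 1 it stood at -0.93, under 2-fold. The feedback list, which includes Cish, ran the other way with a median of 0.81. It passed at the preset correlation but not with an estimated one (adjusted p = 0.132). All 11 DC markers were higher (11 adjusted over the list alone, median 4.75, adjusted p = 1.33e-21, adjusted p = 0.0082 with an estimated correlation).

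Markers of other cells moved with these groups in DC. All 12 granulocyte markers were higher in DC than in the mean of the other populations (12 adjusted over the list alone), with a median of 3.22 (adjusted p = 3.69e-11, but adjusted p = 0.145 with an estimated correlation), and S100a8 was higher by 3.63 ± 0.32. On replicate 2 they lay a median of 1.92 above replicate 1, at least 2-fold for 12 of 12. For each gene the median intensity of the lymphoid populations was then subtracted from DC and GN alike. After that the markers reached between 15.4% and 63.0% of their GN intensity on replicate 2, against 1.7% to 17.6% on replicate 1. Red pulp macrophage markers were higher too, 8 of 10 (8 adjusted over the list alone) with a median of 2.02 (adjusted p = 4.63e-09, adjusted p = 0.137 with an estimated correlation), and were a median of 1.06 higher on replicate 2. Monocyte markers, 5 of 7 higher (5 adjusted over the list alone), had a median of 1.14 (adjusted p = 5.61e-06, adjusted p = 0.0876 with an estimated correlation), or 2.04 without DC replicate 1, and B cell markers, 5 of 10 higher (5 adjusted over the list alone), one of 1.02 (adjusted p = 2.28e-06, adjusted p = 0.128 with an estimated correlation). The macrophage effector list, which shares phagocyte genes with these cells, stood a median of 1.02 above the mean of the 9 populations on DC replicate 1 and 1.87 on replicate 2. Gene by gene, however, its median of replicate 2 minus replicate 1 was 0.11, with 2 of 14 genes at least 2-fold higher. Immediate early genes, which sorting and handling can induce, were higher for 7 of 15 (7 adjusted over the list alone), with Atf3 at 3.52 ± 0.19 and a list median of 1.03 (adjusted p = 0.000324, adjusted p = 0.316 with an estimated correlation). Cell cycle genes were higher for 4 of 13 (4 adjusted over the list alone, median 0.84, adjusted p = 0.000237, adjusted p = 0.388 with an estimated correlation). In total 1525 genes passed in DC, 1048 higher and 477 lower.

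GN stood highest for type I interferon genes. Rsad2 (viperin), an antiviral enzyme, was higher by 3.94 ± 0.21 and Oasl2 by 3.17 ± 0.12, and 18 of 27 type I genes were higher and 3 lower (21 adjusted over the list alone), with a median of 1.53 (adjusted p = 4.03e-06, but adjusted p = 0.327 with an estimated correlation). Of 14 macrophage effector genes 10 were higher (10 adjusted over the list alone), including Acod1, which makes itaconate, by 4.75 ± 0.21 (adjusted p = 1.53e-12), Il15 by 4.64 ± 0.13 and Casp4 by 3.85 ± 0.15, with a median of 1.41 (adjusted p = 4.37e-06, adjusted p = 0.0891 with an estimated correlation). Of 10 feedback genes 6 were higher (6 adjusted over the list alone), such as Il18bp, an IL-18 inhibitor, by 2.62 ± 0.09, Socs3 by 2.59 ± 0.18 and Cd274 by 2.01 ± 0.07, with a median of 1.29 (adjusted p = 0.0117, adjusted p = 0.22 with an estimated correlation). The 12 GTPases moved in both directions, 5 higher and 5 lower (10 adjusted over the list alone): Gbp5, Gbp3 and Gbp7 were higher by 2.20 ± 0.10, 1.73 ± 0.11 and 1.28 ± 0.10, whereas Gbp8, Gbp4 and Gbp11 were lower, at -2.78 ± 0.14, -2.65 ± 0.16 and -2.08 ± 0.13. Gbp2b and Gbp9 did not pass, at -0.47 and -0.27. The list median was -0.37 (adjusted p = 0.67). Of 9 class II genes 5 were lower and 1 higher (6 adjusted over the list alone), with a median of -1.39 (adjusted p = 0.0141, adjusted p = 0.34 with an estimated correlation, and adjusted p = 0.136 without genes whose highest population mean lay below the median value of all genes). Ccl5 was lower, at -3.35 ± 0.21. Immediate early genes were higher for 7 of 15 and lower for 1 in GN (8 adjusted over the list alone, median 0.93, adjusted p = 0.0556), and cell cycle genes higher for 5 of 13 (5 adjusted over the list alone, median 0.91, adjusted p = 0.125). The granulocyte genes Mmp8 and S100a8 were higher by 7.38 ± 0.34 and 7.02 ± 0.32. Il1f9, an interleukin-1 family cytokine, followed, 128-fold higher (adjusted p = 1.44e-13). Gimap4, a GTPase of lymphocyte survival, was lower, at -5.35 ± 0.09 (adjusted p = 5.94e-17). All 12 granulocyte markers were higher (12 adjusted over the list alone, median 6.46, adjusted p = 2.15e-08, adjusted p = 0.219 with an estimated correlation), and 3706 genes passed, 1389 higher and 2317 lower.

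**Figure D4:**
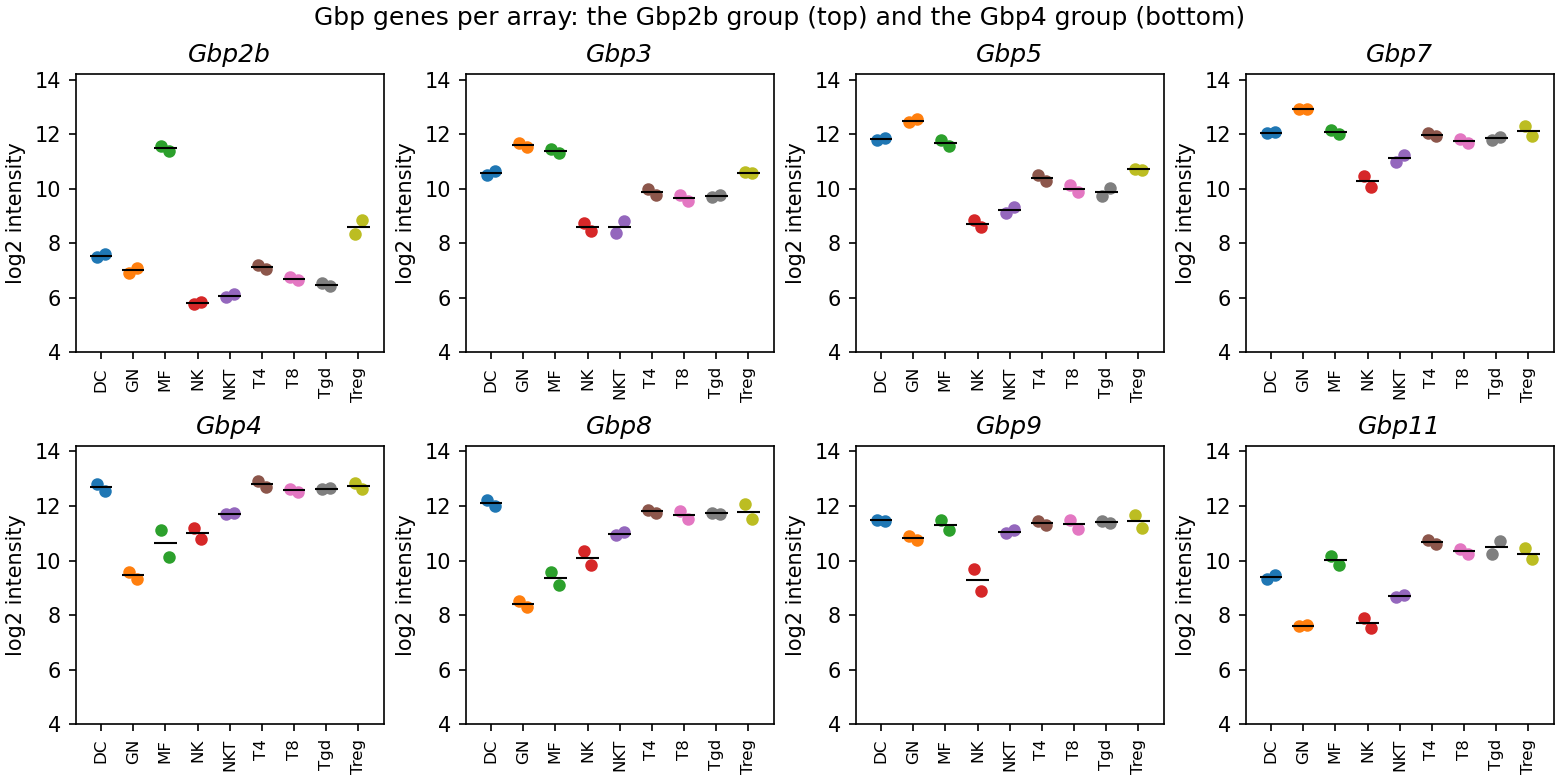
Log2 intensity (y axis) of 8 guanylate-binding protein genes in the 9 sorted populations (x axis), with Gbp2b, Gbp3, Gbp5 and Gbp7 in the top row and Gbp4, Gbp8, Gbp9 and Gbp11 in the bottom row, each point 1 array and each line the mean of 2 arrays. In GN, Gbp5 (12.50) and Gbp7 (12.93) have their highest means and Gbp4 (9.45) and Gbp8 (8.42) their lowest.

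MF, the peritoneal population, had higher macrophage markers, and its GTPase genes went both ways. Vsig4, a complement receptor of resident macrophages, was higher by 7.41 ± 0.12 (adjusted p = 9.88e-18), the lipoxygenase Alox15 by 6.82 ± 0.24 and Serpinb2 by 6.73 ± 0.12, and Ms4a6b was lower, at -5.79 ± 0.09. Gbp2b was higher by 4.56 ± 0.11 (adjusted p = 5.83e-16), Gm4951 by 3.47 ± 0.14 and Iigp1 by 2.25 ± 0.14, whereas Gbp8 and Gbp4 were lower, at -1.73 ± 0.14 and -1.32 ± 0.16. Without MF replicate 3 Gbp4 stood at -0.82, under 2-fold. Of the 12 GTPases 5 were thus higher and 2 lower (7 adjusted over the list alone), with a median of 0.74 (adjusted p = 0.000507, but adjusted p = 0.324 with an estimated correlation). The monocyte-attracting chemokines Ccl2 and Ccl7 were higher by 4.31 ± 0.23 and 3.93 ± 0.20 and Ccl5 was lower, at -4.16 ± 0.21. In all, 6 chemokines of 11 were higher and 2 lower (8 adjusted over the list alone, list median 1.15, adjusted p = 0.0916). Of 14 macrophage effector genes 7 were higher and 1 lower (8 adjusted over the list alone), among them Cybb by 4.25 ± 0.19 and the Fc receptor Fcgr1 by 3.66 ± 0.19, with a median of 1.48 (adjusted p = 8.07e-05, adjusted p = 0.132 with an estimated correlation). The type I genes Ifit2 and Ifit3 were lower, at -3.40 ± 0.11 and -3.06 ± 0.11, in a list with 2 members of 27 higher and 5 lower (7 adjusted over the list alone, median -0.05, adjusted p = 0.585). Class I presentation genes had a median of -0.47 (adjusted p = 0.000423, adjusted p = 0.173 with an estimated correlation), with H2-Q4 the member of 13 that passed, at -1.69 ± 0.07 (1 adjusted over the list alone). Cell cycle genes were higher, 12 of 13 (12 adjusted over the list alone) with Bub1 at 2.53 ± 0.27 and a median of 1.70 (adjusted p = 1.9e-07, adjusted p = 0.24 with an estimated correlation). Of the immediate early genes 2 of 15 were higher and 6 lower (8 adjusted over the list alone, median -0.83, adjusted p = 0.207). All 13 MF markers were higher (13 adjusted over the list alone, median 5.15, adjusted p = 1.1e-16, adjusted p = 0.0154 with an estimated correlation), as were 6 of 10 red pulp macrophage markers, with 2 lower (8 adjusted over the list alone, median 1.90, adjusted p = 0.00347, adjusted p = 0.429 with an estimated correlation). In total 2320 genes passed, 1493 higher and 827 lower.

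NK was low for GTPase and type I interferon genes and high for Ccl3, Ccl4 and Ccl5. Of the 12 GTPases 10 were lower (10 adjusted over the list alone), with Iigp1 at -3.44 ± 0.14, Gm4951 at -2.34 ± 0.14 and Irgm1 at -2.28 ± 0.08, and a median of -1.98 (adjusted p = 1.63e-16, but adjusted p = 0.0587 with an estimated correlation). Of 27 type I genes 20 were lower (20 adjusted over the list alone), including Oas2 at -3.46 ± 0.12 (adjusted p = 6.66e-13) and Ifit1 at -3.11 ± 0.14, with a median of -1.57 (adjusted p = 3.21e-25, adjusted p = 0.0635 with an estimated correlation). Of 10 feedback genes 5 were lower (5 adjusted over the list alone), such as Cd274 at -2.29 ± 0.07, with a median of -0.95 (adjusted p = 2.21e-05, adjusted p = 0.0769 with an estimated correlation). In the class I list, whose median was -0.52 (adjusted p = 1.21e-06, adjusted p = 0.0817 with an estimated correlation), Tap1 was the member of 13 that passed, at -1.10 ± 0.06 (1 adjusted over the list alone). Of the signalling genes 4 of 15 were lower and 1 higher (5 adjusted over the list alone), with Ifngr2 at -3.01 ± 0.09 and Irf8 at 1.60 ± 0.12, and a median of -0.52 (adjusted p = 0.0173, adjusted p = 0.255 with an estimated correlation). Ccl3, Ccl4 and Ccl5 were higher by 3.85 ± 0.31 (adjusted p = 2.65e-08), 3.46 ± 0.15 and 2.96 ± 0.21. The chemokine list had 3 of 11 members higher and 1 lower (4 adjusted over the list alone), and its median of -0.32 differed in sign from its mean of 0.51 and from the direction of the test (adjusted p = 0.88). The NK receptor genes Ncr1, Klra8 and Klrc3 were higher by 6.71 ± 0.17, 6.42 ± 0.18 and 6.13 ± 0.18, and Slfn1 was lower, at -4.12 ± 0.20 (adjusted p = 3.29e-11). All 11 NK markers were higher (11 adjusted over the list alone, median 5.18, adjusted p = 4e-25, adjusted p = 0.0073 with an estimated correlation). Markers of B cells had a median of 0.34 in NK (adjusted p = 0.00696, adjusted p = 0.34 with an estimated correlation). None of them passed, 0 of 10 (0 adjusted over the list alone). Without NK replicate 3 that call was lost (median 0.08, adjusted p = 0.223), and without NK replicate 2 the median was 0.53. Cell cycle genes, 0 of 13 past the threshold (0 adjusted over the list alone, median -0.15, adjusted p = 0.588), had a median of -0.81 for replicate 3 minus replicate 2. In total 1001 genes passed, 484 higher and 517 lower.

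NKT had low Ifngr2, at -2.86 ± 0.09 against the other 8 populations (adjusted p = 4.46e-13), and lower GTPase genes. Of 12 GTPases 5 were lower (5 adjusted over the list alone), with Iigp1 at -1.63 ± 0.14 and Gbp2b 2.84-fold lower (adjusted p = 9.28e-09), and a median of -0.93 (adjusted p = 6.1e-10, but adjusted p = 0.105 with an estimated correlation). Of 14 macrophage effector genes 6 were lower (6 adjusted over the list alone, median -0.74, adjusted p = 1.9e-07, adjusted p = 0.0744 with an estimated correlation), and so were 3 of 9 class II genes (3 adjusted over the list alone, median -0.63, adjusted p = 1.95e-06, adjusted p = 0.0975 with an estimated correlation). Of the 15 signalling genes 3 were lower (3 adjusted over the list alone), Irf8 at -1.98 ± 0.12, with a median of -0.22 (adjusted p = 0.00128, adjusted p = 0.137 with an estimated correlation), or -0.38 without NKT replicate 2. Feedback genes went both ways, 2 of 10 higher and 3 lower (5 adjusted over the list alone), with Socs2 at 2.08 ± 0.16 and Cd274 at -1.46 ± 0.07 (median -0.63, adjusted p = 0.0184, adjusted p = 0.243 with an estimated correlation). The call of that list was lost after a further quantile normalization (adjusted p = 0.0563) and without genes whose highest population mean lay below the median value of all genes (0.0803). Type I genes had 2 of 27 members lower (2 adjusted over the list alone, median -0.12, adjusted p = 0.0562). Ccl5 was higher by 2.55 ± 0.21 (adjusted p = 4.98e-08), in a chemokine list with 1 of 11 members higher and 1 lower (2 adjusted over the list alone). The list median was -0.52 (adjusted p = 0.0258, adjusted p = 0.342 with an estimated correlation). That call was also lost without NKT replicate 2 (adjusted p = 0.0678), with fry (0.107) and with the same filter on dim genes (0.0977). Klrb1c was 32.1-fold higher (adjusted p = 4.46e-13), the chemokine receptor Cxcr6 was higher by 4.71 ± 0.12 and the NK receptor gene Klrc1 by 4.55 ± 0.18, and Cd24a was lower, at -3.19 ± 0.18. Of 13 cell cycle genes 7 were lower (7 adjusted over the list alone, median -1.16, adjusted p = 8.63e-07, adjusted p = 0.267 with an estimated correlation). Without NKT replicate 1 the median of that list was -0.65 (adjusted p = 0.000239). All 8 NKT markers were higher (8 adjusted over the list alone, median 2.72, adjusted p = 3.12e-17, adjusted p = 0.00397 with an estimated correlation), and NK markers, which share Klrb1c with that list, were higher for 6 of 11 (6 adjusted over the list alone, median 1.11, adjusted p = 2.54e-06, adjusted p = 0.0817 with an estimated correlation). In total 773 genes passed, 323 higher and 450 lower.

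Against the mean of the other 8, T4 had higher GTPases and lower chemokines and macrophage effector genes. All 6 lymphoid populations lay below the mean of the 9 for the latter 2 lists, so this was not particular to T4. The GTPase level of T4, at 0.33, lay under those of MF (0.66), Treg (0.60) and DC (0.54). NK (-1.76) and NKT (-0.82) lowered the mean it was set against. Of 12 GTPases 4 were higher (4 adjusted over the list alone), among them Gbp11 by 1.36 ± 0.13 (adjusted p = 2.9e-07) and Iigp1 by 1.31 ± 0.14, with a median of 0.37 (adjusted p = 0.00228, but adjusted p = 0.376 with an estimated correlation). Of 11 chemokines 6 were lower (6 adjusted over the list alone), with Ccl3 at -4.17 ± 0.31 (adjusted p = 1.67e-08) and a median of -1.05 (adjusted p = 3.69e-06, adjusted p = 0.0876 with an estimated correlation). Of 14 macrophage effector genes 7 were lower (7 adjusted over the list alone, median -0.96, adjusted p = 2.15e-08, adjusted p = 0.0587 with an estimated correlation), as were 4 of 9 class II genes (4 adjusted over the list alone, median -0.97, adjusted p = 0.00687, adjusted p = 0.304 with an estimated correlation). Dapl1 was higher by 4.27 ± 0.17, Cd4 by 3.66 ± 0.15 and Igfbp4 by 3.26 ± 0.13. All 8 T4 markers were higher (8 adjusted over the list alone, median 2.59, adjusted p = 1.1e-16, adjusted p = 0.0073 with an estimated correlation). Treg markers moved with them: 6 of 12 were higher (6 adjusted over the list alone, median 1.24, adjusted p = 1.25e-10, adjusted p = 0.0471 with an estimated correlation), with Il2ra at 2.70 ± 0.10 and Foxp3, the transcription factor of regulatory T cells, at 2.15 ± 0.10. The gate given for T4 does not exclude CD25+ cells, so T4 may contain Treg cells. Immediate early genes were lower for 4 of 15 (5 adjusted over the list alone, median -0.53, adjusted p = 0.00397, adjusted p = 0.411 with an estimated correlation), and they were a median of 0.52 higher on replicate 3 than on replicate 2, with Fos at 9.40 and 6.91. Without T4 replicate 2 that call was lost (median -0.08, adjusted p = 0.253), and without T4 replicate 3 the median was -1.05. Cell cycle genes were lower for 1 of 13 (1 adjusted over the list alone, median -0.61, adjusted p = 0.000837, adjusted p = 0.432 with an estimated correlation). In total 731 genes passed, 263 higher and 468 lower.

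T8 was marked by its coreceptor genes. Cd8a was higher by 4.86 ± 0.11 (adjusted p = 1.66e-14), Cd8b1 by 4.73 ± 0.10 and Dapl1 by 4.40 ± 0.17, and Fcer1g, an Fc receptor adaptor of innate cells, was lower, at -3.57 ± 0.12. Of 14 macrophage effector genes 6 were lower (6 adjusted over the list alone), Casp4 at -3.17 ± 0.15 (adjusted p = 7.44e-11), with a median of -0.72 (adjusted p = 4.12e-09, but adjusted p = 0.0531 with an estimated correlation). Of 10 feedback genes 2 were lower (2 adjusted over the list alone, median -0.58, adjusted p = 0.000169, adjusted p = 0.0891 with an estimated correlation). Of 11 chemokines 4 were lower (4 adjusted over the list alone, median -0.55, adjusted p = 0.00976, adjusted p = 0.284 with an estimated correlation). The list call was lost without T8 replicate 2 (adjusted p = 0.0781). H2-Oa, a chain of the class II modulator, was higher by 1.13 ± 0.17 (adjusted p = 6.61e-05), and at 0.96 fell under 2-fold without T8 replicate 3. The class II list had 2 of 9 members higher and 4 lower (6 adjusted over the list alone, median -0.99, adjusted p = 0.139). The GTPases had a median of 0.06 (adjusted p = 0.735). All 8 T8 markers were higher (8 adjusted over the list alone, median 2.54, adjusted p = 1.38e-15, adjusted p = 0.0287 with an estimated correlation). Immediate early genes were lower for 5 of 15 (6 adjusted over the list alone, median -0.73, adjusted p = 0.00538, adjusted p = 0.427 with an estimated correlation), and lay a median of 0.51 higher on replicate 3 than on replicate 2, with Fos at 9.48 and 6.88. Without T8 replicate 2 the list call was lost (median -0.28, adjusted p = 0.203), and without T8 replicate 3 the median was -1.25. In total 875 genes passed, 282 higher and 593 lower.

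The 3 largest named gains of Tgd were in T cell receptor gene segments, of the delta, gamma and alpha chains. Trdv2-2 was higher by 6.49 ± 0.15 (adjusted p = 2.49e-14), Trgv1 by 5.28 ± 0.16 and Trav14-1 by 4.26 ± 0.16, although another probe set of Trav14-1 gave a difference of 0.46, and Entpd1 (CD39) was lower, at -2.59 ± 0.10. Ccl5 was higher by 2.35 ± 0.21 (adjusted p = 2.72e-07) and Ccl3 by 1.89 ± 0.31, whereas Cxcl9 was lower, at -1.45 ± 0.23 (adjusted p = 0.000197), or -0.96 and under 2-fold without Tgd replicate 2. Thus of 11 chemokines 2 were higher and 1 lower (3 adjusted over the list alone, median -0.29, adjusted p = 0.122). Of 14 macrophage effector genes 3 were lower (3 adjusted over the list alone, median -0.54, adjusted p = 3.79e-06, but adjusted p = 0.0891 with an estimated correlation). Of the 12 GTPases 1 was higher and 1 lower (2 adjusted over the list alone, median 0.08, adjusted p = 0.717). Of 6 Tgd markers 4 were higher (4 adjusted over the list alone, median 1.61, adjusted p = 1.39e-11, adjusted p = 0.0471 with an estimated correlation), including Il23r by 4.13 ± 0.12. NKT markers, 4 of 8 higher (4 adjusted over the list alone, median 1.18, adjusted p = 3.19e-10, adjusted p = 0.0073 with an estimated correlation), and NK markers, 4 of 11 higher (4 adjusted over the list alone, median 0.75, adjusted p = 2.68e-06, adjusted p = 0.0817 with an estimated correlation), moved with them. Of 10 B cell markers 2 were higher (2 adjusted over the list alone, median 0.30, adjusted p = 0.00645, adjusted p = 0.34 with an estimated correlation). Their list call was lost without Tgd replicate 3 (median 0.18, adjusted p = 0.0686). Cell cycle genes were lower for 2 of 13 (2 adjusted over the list alone, median -0.75, adjusted p = 1.19e-05, adjusted p = 0.316 with an estimated correlation), with a median of -0.49 without Tgd replicate 2. In total 499 genes passed, 245 higher and 254 lower.

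Treg carried its lineage genes and, against the mean of the other 8, higher GTPases. Its GTPase level of 0.60 lay under that of MF (0.66) and near that of DC (0.54). NK (-1.76) and NKT (-0.82) lowered the mean it was set against. Il2ra was higher by 4.57 ± 0.10, Foxp3 by 4.44 ± 0.10 (both adjusted p = 6.33e-15) and the inhibitory receptor Ctla4 by 4.41 ± 0.28, and the lipid flippase gene Atp8b4 was lower, at -4.30 ± 0.11. The cytokine signalling inhibitors Socs2 and Cish were higher by 2.05 ± 0.16 (adjusted p = 2.38e-08) and 1.77 ± 0.17, and another probe set of Socs2 gave 1.08. They were the 2 members of 10 feedback genes that passed (2 adjusted over the list alone). Of 12 GTPases 4 were higher (4 adjusted over the list alone), with Iigp1 and Gbp2b both at 1.32, and a median of 0.67 (adjusted p = 2.15e-08, but adjusted p = 0.133 with an estimated correlation). Class I genes had a median of 0.22 (adjusted p = 5.72e-05, adjusted p = 0.129 with an estimated correlation). Of 11 chemokines 4 were lower (4 adjusted over the list alone), Ccl3 at -4.22 ± 0.31 (adjusted p = 1.4e-08), with a median of -0.81 (adjusted p = 2.68e-06, adjusted p = 0.0841 with an estimated correlation), and so were 5 of 14 macrophage effector genes (5 adjusted over the list alone, median -0.72, adjusted p = 4.65e-06, adjusted p = 0.0891 with an estimated correlation), with a median of -0.47 without Treg replicate 2. All 12 Treg markers were higher (12 adjusted over the list alone, median 3.14, adjusted p = 3.81e-28, adjusted p = 0.0073 with an estimated correlation), and T4 markers were higher for 6 of 8 (6 adjusted over the list alone, median 1.93, adjusted p = 7.07e-16, adjusted p = 0.0073 with an estimated correlation). In total 736 genes passed, 297 higher and 439 lower.

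Over all 10 contrasts and 8 interferon lists, 55 of 80 camera tests passed, and 2 held with an estimated correlation, class II genes in DC and macrophage effector genes in DC. The first is no independent result, because DC were sorted on MHC class II. The macrophage effector level stood at 1.02 on DC replicate 1 and at 1.87 on DC replicate 2, the array with more granulocyte transcripts. Gene by gene, the median of replicate 2 minus replicate 1 was only 0.11, with 2 of 14 genes at least 2-fold higher. Markers of cells outside the sorts were tested too. Of the eosinophil and mast cell markers 5 of 11 (5 adjusted over the list alone), of the plasmacytoid dendritic cell markers 4 of 6 (4 adjusted over the list alone), of the red cell and platelet markers 3 of 7 (3 adjusted over the list alone) and of the stromal and mesothelial markers 1 of 10 (1 adjusted over the list alone) passed the test over the 9 populations, against 7 of 7 monocyte (7 adjusted over the list alone), 10 of 10 red pulp macrophage (10 adjusted over the list alone) and 5 of 10 B cell markers (6 adjusted over the list alone). Plasmacytoid markers had a median of 0.40 in Tgd (adjusted p = 0.000855, adjusted p = 0.129 with an estimated correlation), and red cell and platelet markers one of 0.31 in DC (adjusted p = 0.141). The 4 plasmacytoid markers that passed were highest in different populations, Ccr9 in Tgd, Pacsin1 in T4, Tcf4 in MF and Siglech in DC. So were the 5 eosinophil and mast cell markers, Siglecf and Ccr3 in GN, Cpa3 in Tgd, Kit in DC and Cma1 in NK. These calls therefore need not mean stray cells. Stromal markers had their largest median in GN, at 0.30 (adjusted p = 0.294).

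Myeloid populations (DC, GN and MF) were set against the 6 lymphoid ones. Ifitm6 was higher in the myeloid populations by 6.46 ± 0.08, Pla2g7 by 6.00 ± 0.09, the chemokine receptor Ccr1 by 5.97 ± 0.17 and Spi1 (PU.1), a transcription factor of myeloid cells, by 5.68 ± 0.09 (adjusted p = 1.14e-18). Wfdc17, Serpinb10, Fcgr4, Alox5ap, Bst1 and Pstpip2 were higher by between 5.39 and 5.76. Gimap3 (-6.37 ± 0.07), Cd3g (-6.33 ± 0.11), Ms4a4b (-6.08 ± 0.07), Gimap4 (-5.96 ± 0.06) and Cd96 (-5.86 ± 0.07) were lower, as were the cytokine receptor chains Il2rb (-5.49 ± 0.11) and Il7r (-5.31 ± 0.08) and the costimulatory genes Cd27, Cd2 and Cd28, at -5.19, -5.17 and -5.04. Among the fixed lists, 9 of 14 macrophage effector genes were higher (9 adjusted over the list alone), with Cybb at 5.21 and a median of 2.00 (adjusted p = 4.12e-09, but adjusted p = 0.0531 with an estimated correlation). Type I genes were higher for 11 of 27 (11 adjusted over the list alone, median 0.78, adjusted p = 1.37e-07, adjusted p = 0.27 with an estimated correlation), class II genes for 6 of 9 (6 adjusted over the list alone, median 2.12, adjusted p = 0.000223, adjusted p = 0.179 with an estimated correlation) and feedback genes for 5 of 10 (5 adjusted over the list alone, median 1.01, adjusted p = 0.00181, adjusted p = 0.137 with an estimated correlation). Of the chemokines 7 of 11 were higher, such as Cxcl9 by 3.60, and 1 lower, Ccl5 at -2.52 (8 adjusted over the list alone, median 1.36, adjusted p = 0.000595, adjusted p = 0.173 with an estimated correlation). Signalling genes were higher for 4 of 15 (4 adjusted over the list alone), Ifngr2 by 1.95, with a median of 0.45 (adjusted p = 0.000752, adjusted p = 0.129 with an estimated correlation). GTPases were higher for 6 of 12 and lower for 2 (8 adjusted over the list alone), Gbp5 at 2.18 and Gbp4 at -1.32, with a median of 0.93 (adjusted p = 0.00528, adjusted p = 0.416 with an estimated correlation). The myeloid populations did not move alike. Against the mean of the 9, the GTPase level was 0.54 in DC, 0.66 in MF and -0.33 in GN. It was 0.60 in Treg, 0.33 in T4, 0.07 in Tgd and 0.05 in T8. NK (-1.76) and NKT (-0.82), which also had the lowest Ifngr2, lowered the lymphoid mean. The class II level was lowest in GN (-1.23), and the type I level of MF was -0.04. Class I genes had a median of -0.10 (adjusted p = 0.813). Cell cycle genes moved with the myeloid side, 10 of 13 higher (10 adjusted over the list alone, median 1.48, adjusted p = 5.95e-06, adjusted p = 0.304 with an estimated correlation). In total 2135 genes passed, 1263 higher and 872 lower.

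MF and DC, both antigen-presenting cells, differed in tissue as well as in type. In MF, Prg4 was higher by 7.57 ± 0.37, Vsig4 by 7.55 ± 0.16, Alox15 by 7.03 ± 0.33, the endothelin receptor gene Ednrb by 6.81 ± 0.13 and Retnla by 6.70 ± 0.14 (adjusted p = 8.95e-16). Klri1, Gpr141, Dnase1l3, Havcr2 and Apol7c were lower, at -7.47 ± 0.17, -6.96 ± 0.22, -6.94 ± 0.19, -6.52 ± 0.16 and -6.46 ± 0.13. Of 9 class II genes 8 were lower (8 adjusted over the list alone), among them H2-Oa at -4.59, H2-Ob at -4.48 and H2-Eb1 at -4.10 ± 0.25 (adjusted p = 4e-10). Of 27 type I genes 8 were lower (8 adjusted over the list alone), with Ifit2 at -4.50 ± 0.15 and Ifit3 at -4.28 ± 0.15. Of the chemokines 3 were higher and 7 lower (10 adjusted over the list alone), Ccl5 at -5.34 ± 0.28. All 13 MF markers were higher and all 11 DC markers lower (13 and 11 adjusted over the list alone), and 11 of 12 granulocyte markers were lower in MF as well (11 adjusted over the list alone). In total 2146 genes passed, 1164 higher and 982 lower.

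GN and DC differed in 3336 genes, 1139 higher and 2197 lower in GN. H2-Ab1 was lower in GN, at -6.35 ± 0.28 (adjusted p = 6.89e-12), as were H2-Aa (-5.92 ± 0.37), H2-Ob (-5.21 ± 0.17), Ciita (-4.90 ± 0.12), H2-Oa (-4.75 ± 0.23) and H2-Eb1 (-4.73 ± 0.25), and 8 of 9 class II genes in all (8 adjusted over the list alone). Klri1, Dnase1l3, Slamf7 and the immunoglobulin segment Igkv10-96 were lower, at -7.17, -6.08, -6.03 and -6.20. Sycp2 was higher by 4.40 ± 0.29, Ceacam10 by 4.17 ± 0.16, Stfa2 by 4.12 ± 0.14, Scrg1 by 4.03 ± 0.18 and Mgst1 by 4.02 ± 0.41 (adjusted p = 2.26e-07). Of 12 GTPases 5 were lower and 1 higher (6 adjusted over the list alone), 5 of 10 feedback genes were higher and 2 lower (7 adjusted over the list alone), and 6 of 27 type I genes were higher and 3 lower (9 adjusted over the list alone). All 12 granulocyte markers were higher (12 adjusted over the list alone), by a median of 2.89 when set against DC arrays that also held these transcripts.

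NKT and NK shared low Ifngr2 and differed in T cell and NK genes. In NKT the chemokine receptor genes Cxcr6 and Ccr9 were higher by 5.30 ± 0.16 and 4.80 ± 0.20, Atp8a2 by 4.65 ± 0.11, Themis, of T cell receptor signalling, by 4.57 ± 0.16 and Inpp4b by 4.51 ± 0.12. Sh2d1b1, Klra8, the granzyme gene Gzma, Car5b and Klri2 were lower, at -6.09 ± 0.17, -5.69 ± 0.25, -4.98 ± 0.30, -4.74 ± 0.25 and -4.68 ± 0.13. Of 27 type I genes 15 were higher in NKT (15 adjusted over the list alone), among them Ifit1 by 3.48 ± 0.18 and Ifi27l2a by 2.88 ± 0.21, as were 4 of 12 GTPases (4 adjusted over the list alone). Ccl4, Ccl3, Irf8 and Casp1 were lower, at -3.76 ± 0.20, -3.34 ± 0.41, -3.19 ± 0.16 and -2.77 ± 0.14. Of 11 NK markers 9 were lower and 5 of 8 T4 markers higher (9 and 5 adjusted over the list alone). In total 726 genes passed, 299 higher and 427 lower.

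T8 and T4 differed in 190 genes, 84 higher and 106 lower in T8. Cd8a was higher by 5.41 ± 0.15, Plac8 by 3.60 ± 0.22, Cd8b1 by 3.43 ± 0.13, Klra6 by 3.40 ± 0.21 and the integrin gene Itgae by 3.25 ± 0.23. Cd4 was lower, at -5.48 ± 0.19, followed by St8sia6 (-4.15 ± 0.13), Il2ra (-4.13 ± 0.13), Cd40lg (-3.96 ± 0.13) and Zbtb7b, the transcription factor of the CD4 lineage (-3.68 ± 0.13). Of interferon-list genes, Ccl3 and Ccl5 were higher by 2.64 ± 0.41 (adjusted p = 0.000652) and 1.86 ± 0.28 and H2-Oa by 1.61 ± 0.23, and Socs2, Casp4 and Cish were lower, at -2.08 ± 0.21, -1.41 ± 0.20 and -1.15 ± 0.23. The call of Cish (adjusted p = 0.00687) was lost without T4 replicate 3 (adjusted p = 0.0716) or T8 replicate 2 (adjusted p = 0.0752), and another probe set of Socs2 gave -0.72. Of 12 Treg markers 8 were lower in T8 (8 adjusted over the list alone).

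Treg and T4 differed in 173 genes, 103 higher and 70 lower in Treg. Lrrc32 (GARP), which presents latent TGF-beta, was higher by 2.50 ± 0.17, Socs2 by 2.25 ± 0.21 and Coro2a by 2.16 ± 0.17. Another probe set of Socs2 gave 1.29. Flicr and the transcription factor Ikzf2 (Helios) were each higher by 2.08 (adjusted p = 1.47e-07 and 1.03e-06). Pde3b, Atp8b4, Vipr1, Klrd1 and Lypd6b were lower, at -3.71 ± 0.18, -3.54 ± 0.15, -3.06 ± 0.13, -3.06 ± 0.13 and -2.88 ± 0.15, and another probe set of Vipr1 gave -0.73. Of interferon-list genes, Cish and Gbp2b were higher by 1.61 ± 0.23 and 1.47 ± 0.14, and Oas2 was lower, at -1.02 ± 0.17 (adjusted p = 0.00104). It stood under 2-fold without T4 replicate 2 (-0.82) or Treg replicate 3 (-0.98). Of 12 Treg markers 11 were higher (11 adjusted over the list alone). T4 itself held Foxp3 at 9.97 ± 0.05, against 12.01 ± 0.25 in Treg. The gate given for T4 does not exclude CD25+ cells, so these populations may overlap and the differences may be understated.

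Tgd differed from the mean of T4 and T8 in 290 genes, 229 higher and 61 lower. With each array centred on its median the split was 191 higher and 87 lower. Trdv2-2 was higher by 6.49 ± 0.17, Klri1 by 5.65 ± 0.15, Trgv1 by 5.64 ± 0.18, Klrc1 by 4.74 ± 0.21 and the IL-23 receptor gene Il23r by 4.48 ± 0.14. The alpha and beta receptor segments Trav12-2, Trav7d-4, Trav19 and Trbv1 were lower, at -3.44 ± 0.23, -2.71 ± 0.21, -2.28 ± 0.13 and -1.94 ± 0.13, as was Als2cl at -3.37 ± 0.11, for which another probe set gave -0.94. Ccl3 and Ccl5 were higher by 4.07 ± 0.36 and 2.22 ± 0.24, Casp1 by 2.21 ± 0.12, Il15 by 2.05 ± 0.15 and Casp4 by 1.53 ± 0.18. Rsad2 was higher by 1.30 ± 0.24 (adjusted p = 0.00157), a call that was lost without Tgd replicate 3 (adjusted p = 0.0693). Of the chemokines 2 were higher (3 adjusted over the list alone), of the type I genes 4 of 27 were higher and 1 lower (5 adjusted over the list alone), and of the macrophage effector genes 3 of 14 were higher (3 adjusted over the list alone). Of 11 NK markers 8 were higher as well (8 adjusted over the list alone).

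Receptor and kinase levels were set against the GTPase level, the median over the 12 GTPases of a population's mean minus the mean of all 9. That level ran from -1.76 in NK and -0.82 in NKT to 0.66 in MF. For Ifngr2 over the 9 populations Pearson's r was 0.815 (two-sided permutation p = 0.0128, adjusted p = 0.051 over 4 relations) and Spearman's rho 0.5 (permutation p = 0.175, adjusted p = 0.234). Without NK and NKT, the 2 populations farthest from the median of Ifngr2, r was 0.008, so the relation rested on them. Its adjusted p passed the threshold without any 1 of 7 arrays, DC replicate 1 (0.0488), GN replicate 1 (0.0487), NK replicate 3 (0.0462), NKT replicate 2 (0.0499), T8 replicate 2 (0.0469), Tgd replicate 3 (0.0497) or Treg replicate 3 (0.0486). Over the 6 lymphoid populations r was 0.94 (permutation p = 0.00556, adjusted p = 0.0222) and rho 0.886 (permutation p = 0.0333, adjusted p = 0.117). NK and NKT are 2 of these 6, and the lymphoid set was not run without them, so this is no independent result. Ifngr1 ran the other way, with r = -0.638 (permutation p = 0.0592, adjusted p = 0.0789) and rho = -0.567 (permutation p = 0.122, adjusted p = 0.234), and r = -0.153 without MF and NK. Jak1 had r = -0.671 (permutation p = 0.0455, adjusted p = 0.0789) and rho = -0.817 (permutation p = 0.0116, adjusted p = 0.0463), and r = -0.737 without DC and MF. The adjusted p of its rho was 0.204 after a further quantile normalization, 0.0698 after median centring, and 0.128, 0.0713, 0.0723 and 0.128 without GN replicate 1, MF replicate 2, NKT replicate 1 and Treg replicate 3. Jak2 had r = 0.04 (permutation p = 0.92, adjusted p = 0.92) and rho = -0.133 (permutation p = 0.747, adjusted p = 0.747), and r = 0.026 without DC and NKT.

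**Figure D5:**
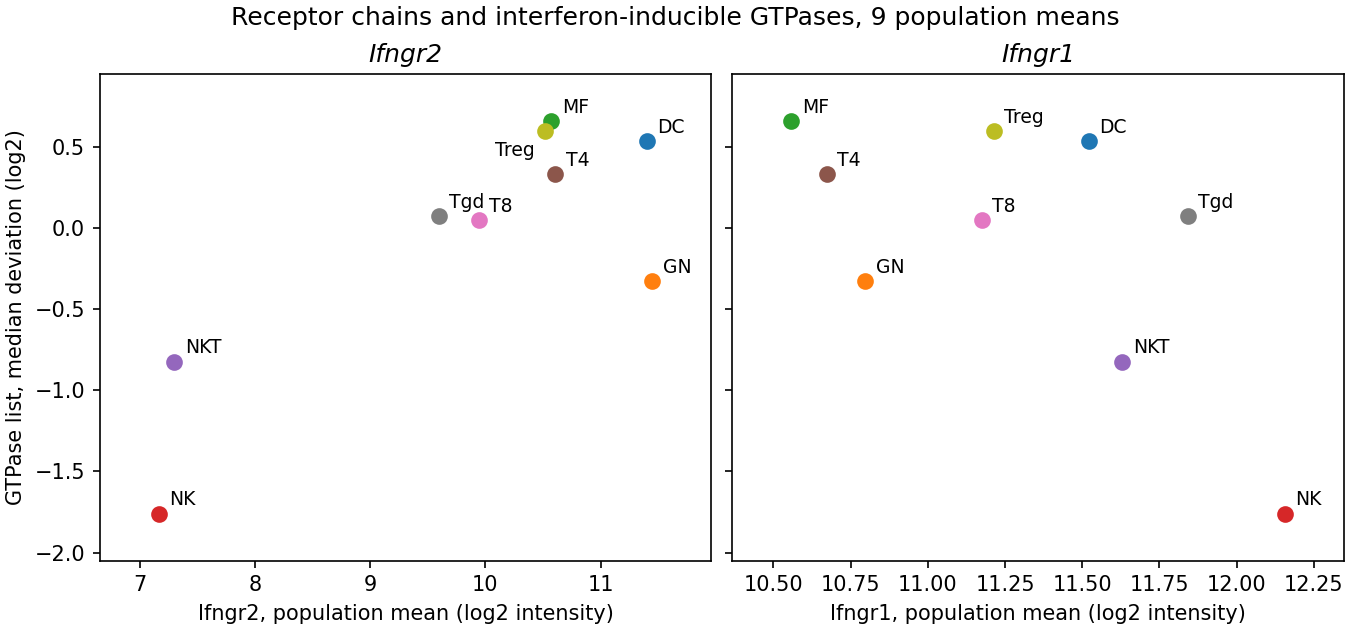
GTPase level (y axis, median log2 deviation over 12 genes) against the population mean of Ifngr2 or Ifngr1 (x axis, log2 intensity), with each point 1 of 9 populations. NK and NKT lie apart at low Ifngr2, with GTPase levels of -1.76 and -0.82, and r for Ifngr2 is 0.815 with them and 0.008 without them.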

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

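The sets without the DC arrays or the immediate early genes, the correlations with 1 array left out, and lists outside the interferon lists with 1 array left out, were chosen after the data were seen, and the other alternatives before. No alternative reversed a gene or list call. Without a minimum fold more genes passed. There were 13694 over the 9 populations, 5204 over the lymphoid ones and 10259 for myeloid against lymphoid. In single populations there were 6711 for DC, 12991 for GN, 9432 for MF, 5347 for NK, 4433 for NKT, 5307 for T4, 5941 for T8, 3604 for Tgd and 4078 for Treg. In the further contrasts there were 6609 for MF against DC, 11450 for GN against DC, 3048 for NKT against NK, 686 for T8 against T4, 634 for Treg against T4 and 1799 for Tgd against T4 and T8. The fit was otherwise unchanged, so the added genes are those under 2-fold. Each other setting, and each array left out, kept the counts it was run on within 1.5 times. These were all 18 counts, except 7 with only the populations compared, 15 without the DC arrays and 5 without the immediate early genes. With 1 array left out, where the lone array was assumed to vary like the others, the myeloid count lay between 2098 and 2199, and that of T8 against T4 between 179 and 219. Without the DC arrays 2641 genes passed for myeloid against lymphoid (1428 higher and 1213 lower), and without the immediate early genes 727 passed for T4 and 870 for T8.

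Of the 55 interferon list calls 2 held with an estimated correlation. Other settings ended 11 of the calls. A further quantile normalization ended those of signalling genes in GN (adjusted p = 0.0619, against 0.00976) and feedback genes in NKT (0.0563) and Tgd (0.14, against 0.0173). The median of the signalling genes in GN went from 0.68 to 0.37. The filter on dim genes at the median of all values ended those of feedback genes in NKT (0.0803) and Tgd (0.0684), class I genes in T4 (0.056), class II genes in GN (0.136) and Treg (0.0719) and chemokines in NKT (0.0977), and fry those of chemokines in NKT (0.107) and type I genes in Tgd (0.14). With an array left out the calls lost were class II genes in Treg without Treg replicate 2 (adjusted p = 0.276), type I genes in T8 without T8 replicate 3 (0.442) and in Tgd without Tgd replicate 3 (0.131), feedback genes in Treg without Treg replicate 3 (0.0865), and chemokines in T8 without T8 replicate 2 (0.0781) and in NKT without NKT replicate 2 (0.0678). The cause was not tested. With 1 array left out, between 54 and 57 list tests passed. Of the 289 named differences, 7 lost their call, each with 1 array left out. By adjusted p these were Cish in T8 against T4 (0.0716 and 0.0752) and Rsad2 in Tgd against T4 and T8 (0.0693). The other 5 fell under 2-fold: Cish in DC (-0.93), Gbp4 in MF (-0.82), H2-Oa in T8 (0.96), Cxcl9 in Tgd (-0.96) and Oas2 in Treg against T4 (-0.82 and -0.98). Named differences were run under 4 settings and with each array left out. Another scaling moved the median of all genes by between -0.097 and 0.087.

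For Ifngr2 and the GTPase level r was 0.822 with the list mean (adjusted p = 0.0417) and 0.94 over the lymphoid populations, and with 1 array left out it lay between 0.801 and 0.827, past the threshold in the 7 of 18 cases that the report names. For Jak1 it was -0.86 over the lymphoid populations, where it passed (adjusted p = 0.0472, against 0.0789 over all 9), and with 1 array left out it lay between -0.695 and -0.642. For Jak2 it lay between -0.038 and 0.118, with -0.038 without NK replicate 3, and for Ifngr1 between -0.656 and -0.619. The cause was not tested.

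With the replicate number as a block, 2185 genes passed for myeloid against lymphoid and 7709 over the 9 populations, and 56 list tests passed. Same-numbered arrays did not deviate together throughout: of 18 pairs of populations that share both numbers, 11 had a correlation over 0.1, within a range from -0.189 to 0.4, and 13 of 18 arrays correlated best with an array of their own number. Immediate early genes were a median of 0.52 higher on replicate 3 than on replicate 2 in T4, 0.51 in T8, 0.46 in NK, 0.32 in Treg, 0.22 in MF and 0.06 in Tgd. GTPases went the other way, with medians of -0.38 in NK, -0.22 in MF, -0.20 in T8, -0.20 in Treg and -0.15 in T4, but 0.04 in Tgd. With pairs at or under 0.1, the numbers were not taken to pair the arrays, but a shared batch was not excluded. DC, GN and NKT carried the numbers 1 and 2 and the other populations 2 and 3. Number and population can therefore not be fully told apart. The block ended no call of a named gene or list, while 1 further list test passed with it.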

Other observations

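The fits with a further quantile normalization and the correlation without the 2 farthest populations were fixed before the data were seen. Their use as tests of explanations, and the other tests of this part, were chosen after the results were seen, and the genes of the next paragraph were chosen after their values were seen.

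Single genes known from other cell types stood high in some populations on both arrays. Kit, the stem cell factor receptor, stood at 12.13 and 11.96 in DC and at 9.10 and 9.52 in Tgd, with 6.23 ± 0.04 in MF. Cma1, a mast cell protease gene, stood at 9.13 and 9.55 in NK and at 5.63 or below elsewhere. Mmp9, a granulocyte protease gene, stood at 10.66 and 10.42 in NKT, against 12.98 and 13.01 in GN. Pf4, best known from platelets, stood at 12.58 and 12.39 in MF. Nos2, the inducible nitric oxide synthase of activated macrophages, lay between 6.56 and 6.80 in all 9 populations, 6.56 ± 0.03 in MF. Fos differed between the arrays of T4 (6.91 and 9.40) and T8 (6.88 and 9.48), as did Dusp1 (9.21 and 11.47 in T4, 8.73 and 11.19 in T8).

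NK and NKT had both the lowest Ifngr2 and the lowest GTPase levels, and a candidate explanation is that this receptor chain limits the GTPase level. Without NK and NKT, r between Ifngr2 and the GTPase level was 0.008, so that these 2 populations carried the relation and this explanation cannot be told apart from any other difference between them and the rest. The GTPase median of NK was -2.04 after a further quantile normalization. The values were already normalized, and this step moved the median of all genes by between -0.081 and 0.044 over the contrasts. It could therefore not decide on scaling of the arrays. Lower baseline expression and a weaker response stay open, as untested, because untreated arrays were not analysed here.

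In GN the measured guanylate-binding protein genes split largely by their place in the genome. Gbp3, Gbp5 and Gbp7 were higher than in the other 8 populations, and Gbp4, Gbp8 and Gbp11, on another chromosome, were lower. Gbp2, Gbp6 and Gbp10 had no probe set with 1 symbol and were not measured. A member of each group did not pass, Gbp2b at -0.47 beside the first and Gbp9 at -0.27 beside the second, where the median of all 4 was -2.36. After a further quantile normalization the medians were 1.28 and -2.20 and the gap 3.48. The values were already normalized, and this step moved the median of all genes by between -0.081 and 0.044 over the contrasts. It could therefore hardly change the gap and does not decide on scaling. Whether GN hold a different baseline or respond differently stays open and may depend on how each group of genes is regulated, which was not tested.

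Granulocyte genes were higher in the DC arrays, more so on replicate 2, and granulocytes that passed the gate on CD11c, MHC class II and Flt3 are a candidate source. Over 82 other genes at least 8-fold higher in GN than in MF and each lymphoid population, none on the marker list, the median of replicate 2 minus replicate 1 was 0.75, with 77 higher and 31 at least 2-fold, in line with RNA of granulocytes. S100a8, among the most abundant, stood at 9.26 and 11.31 in DC and 13.23 and 13.36 in GN. An equal gain of all other cells was argued against by a gap of 2.01 between the granulocyte and T4 marker medians, but red pulp macrophage (1.06), monocyte (0.77), red cell and platelet (0.65) and NK markers (0.58) were also higher on replicate 2. A gain of several cell types and expression by DC themselves stay open.

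The count for myeloid against lymphoid populations was set against splits that kept both arrays of a population together. Of the 84 splits of the 9 populations into 3 and 6, the real one gave the most genes, 2135. The highest other, which set GN, MF and NK apart, gave 1418. The populations were grouped by known lineage and are not interchangeable, so these splits cannot exclude chance.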
